A study of Zea mays with 21 samples.

How the data were processed

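Roots of maize (Zea mays, line PR33T56 per the labels) were measured on 1-colour microarrays, 21 arrays in 7 groups of 3. Per the labels, 6 seedlings shared a pot of 1.8 L of nutrient solution, with 1 pot per treatment. The roots of 3 seedlings of a pot were pooled after 24 h, and the experiment was done 3 independent times. The complete solution (Control) held 0.1 mM KH2PO4 as its phosphate and 100 uM FeNaEDTA, a chelated ferric iron. KH2PO4 was left out in P-deficient, P-nano and P-bulk, and FeNaEDTA in Fe-deficient, Fe-nano and Fe-bulk. The nano groups received FePO4 nanoparticles and the bulk groups ordinary FePO4 in place of the nutrient left out. The dose of FePO4 is not given in the sources used here.

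Per the labels, Cy3-labelled cRNA was made from 200 ng of RNA. Feature Extraction 10.5.1.1 read the scans, per the submitters' processing notes. The deposited scanner files give the intensity of each spot on a linear scale. Per the file headers, the processed signal was background-subtracted and detrended within each array, and it was not scaled between arrays. The scanner's marks for spots above background, saturated or non-uniform come from the same deposited files. The authors' value table is also an intensity, equal to the processed signal times 1 constant per array, with a 75th percentile between 573.5 and 573.9. Its scale is therefore linear, its genes are not centred, and it holds levels of single arrays, so no ratio direction is left unknown. Its medians for replicates 1, 2 and 3 were 97.93, 89.29 and 81.68 in Control, 87.08, 99.42 and 77.19 in P-deficient, 78.31, 87.38 and 89.24 in P-nano, and 89.98, 91.01 and 84.42 in P-bulk. They were 91.29, 98.19 and 103.42 in Fe-deficient, 116.9, 91.69 and 94.28 in Fe-nano, and 100.23, 95.81 and 88.85 in Fe-bulk. As its constants cancel in the scaling, this table gave the same calls by construction.

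The log2 of each processed signal was taken and the log2 of the array's 75th percentile was subtracted, so that a difference of 1 is a doubling. The 768 spots marked as non-uniform (590 probes, 0.093% of the values) were left out. There were 0 saturated spots. Of 39372 probes, 1 per gene model, 32167 were well above background on all 3 arrays of at least 1 group and were tested, and 7205 were left out. Through its gene model, a probe was named from a RefSeq gene table. There 18207 probes matched 1 gene, 519 several and 20646 none, and 2506 had an informative name. The table gives symbols and no product descriptions were used, so a symbol stands for its gene and does not establish its function. No coordinates are given, since the build of the gene models is not given in the sources used here.

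Changes were tested with limma 3.58.1 in R 4.3.3 (lmFit and eBayes) with 1 mean per group over all arrays, 14 residual degrees of freedom and a prior worth 2.47. Adjusted p-values are Benjamini-Hochberg values over the probes tested in a comparison, and an adjusted p under 0.05 was a call. SE is the moderated standard error and intervals are 95% confidence intervals. Only limma was run. There were 14 comparisons: each deficiency against Control and against the other, each FePO4 form against its deficiency, against Control and against the other form, and the difference between nano and bulk compared across the P and Fe supply. The groups, the gene lists, these tests, the rule for named genes and most alternative settings were fixed before the data were examined. As fixed, the lists and the rule also drew on product descriptions. Since none were used, the lists were matched by symbol alone and the rule asked for an informative name instead.

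The 29 gene lists were tested with limma's camera, which compares a list with all other genes, at a preset correlation of 0.01 and two-sided. It used the brightest tested probe of each of 15634 genes and adjusted over the lists of a comparison. A left-out spot was replaced by its group mean. The 21 lists with at least 3 tested genes entered. The lists of acid phosphatases and of membrane lipid remodelling matched 0 genes by symbol, and 6 lists had 1 or 2 tested genes, which are given singly. Each test was repeated with a correlation estimated from the list's own genes, and 0 of the 13 list calls held at an adjusted p under 0.05 in that form, while 4 had an unadjusted p under 0.05.

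The rule for named genes took, from called probes with an informative name whose groups did not overlap, the 6 largest rises and 6 largest falls. It took 3 and 3 in the comparisons of FePO4 with Control and of the deficiencies. To these it added up to 3 called members per list, and for the phytosiderophore, Pi transport and Pi signalling lists the member with the smallest p. The only called probe had no informative name. It, and the list members not given as the smallest p of their list, were chosen after their values were seen. A probe well above background on no array of a group has only a bound there. Its fold is then given as at least the mean of the brighter group over the mean, per array, of the higher of the probe's own signal and the lowest signal well above background.

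On data simulated for P-deficient against Control with 32167 probes, limma recovered 28%, 64%, 86% and 88% of 50 probes changed by 1, 2, 3 and 4 log2 units, and called 7 unchanged probes. In the same simulated comparison a list shifted by -1 had a camera adjusted p of 6.5e-07, and 0 other lists were called. The simulated noise was independent between probes and between arrays. It held no correlation of genes and no slide differences, so these rates may not carry over to the real arrays. In the real arrays a probe of typical spread needed a change of 2.08 to be called if no other probe was, or 2.94 in the comparison across supplies. Less is needed where other probes are called too. The number of arrays limits the precision.

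The file headers give a scan day and a slide number. There were 3 scan days, called days 1 to 3. There were 4 slide numbers, of which 2 recurred on 2 days, and each combination of number and day was taken as a slide, which made 6 (slides 1 to 6). Whether a number on 2 days is 1 slide or 2 is not given in the sources used here. Each slide and each day held more than 1 group, so both were tried as blocks. P-nano shared 0 slides with Control.

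The alternatives fixed at that point were quantile normalization, no filter, a filter on all 21 arrays, an added limit of 1 on the log2 change, only the arrays compared, a replicate block, a slide block, trend and robust moderation, the authors' table, a mean over a gene's probes, an estimated correlation, and leaving out each array. A normexp correction, also fixed then, needs a mean signal, which was not among the columns used here, so it was run on the median signal with an offset of 50. That form was added after seeing the data. So were the scan day block, the slide block for lists, array weights, keeping the non-uniform spots, leaving out Fe-nano replicate 1 everywhere, and comparisons that pool groups. Normexp moved the median change of all probes to between -0.73 and 0.71 and quantile normalization shifted it by -0.11 in Fe-nano against Control and by 0.14 across supplies. The direction of every called list was the same under both. Correlations of changes that share a group were set against 100 simulated draws of unchanged groups. Tables and figures were made with Python 3.11.15, pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9.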

Results

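Root transcripts of maize seedlings were measured after 24 h in a complete solution, without phosphate, without iron, or with FePO4 as the source of the nutrient left out, as nanoparticles or in bulk form. There were 3 arrays per group. The 75th percentile of the signal ran from 195.01 (Fe-bulk replicate 3) to 922.23 (Fe-bulk replicate 1), and between 69.47% and 89.77% of probes were well above background. Over the tested probes, arrays of 1 group were no more alike than arrays of different groups, with a median correlation across genes of 0.972 for both. Only 2 of the 21 arrays had their highest correlation with an array of their own group. Fe-nano replicate 1 stood apart, with a median correlation of 0.949 against 0.958 to 0.98 for the others.

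**Figure D1:**
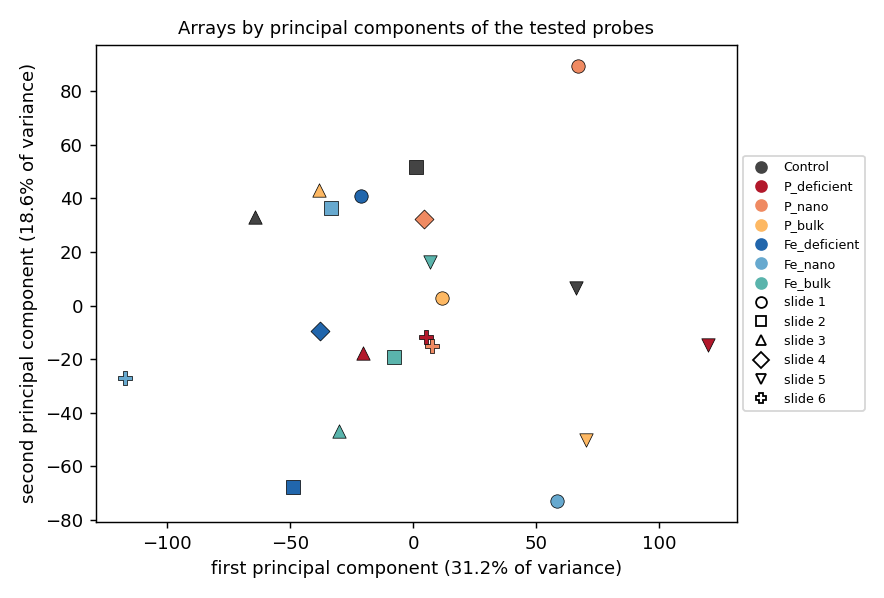
Each point is 1 array placed by the first (31.2% of variance) and second (18.6% of variance) principal components of the tested probes, with colour for the group and marker shape for the slide. The 3 arrays of a group do not lie together.

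Phosphate withdrawal was compared with the complete solution to ask which root genes respond within 24 h. Genes that make and move phytosiderophores, the iron chelators that grasses secrete, fell as a group in P-deficient roots. The median change of the 8 genes was -1.63, and 7 of them were lower. The largest difference was in naat1, the nicotianamine aminotransferase, at -3.83 ± 0.6 (SD, n = 3) in Control and -6.21 ± 0.59 in P-deficient roots, a 5.2-fold difference. That P-deficient level is close to the lowest signal well above background on the P-nano arrays (mean -6.28). The fold of naat1 may therefore rest on a dim signal. The nicotianamine synthases nas1 and nas2 differed by -1.83 (SE 0.68) and -2.33 (SE 0.79), ys1, which takes up ferric phytosiderophore, by -1.43 (SE 0.5), and YS3, linked to phytosiderophore secretion, by -2.21 (SE 0.82). DMAS1, the deoxymugineic acid synthase, differed by -1.09 (SE 0.32), while the transporters ysl11 and ysl12 differed by -0.13 and 0.11. Limma's camera gave the list an adjusted p of 6.5e-06, and adjusted p = 0.264 with an estimated correlation. With normexp the median was -0.56. Adjusted over the list alone 6 of the 8 genes passed limma's test, and over all probes 0 passed, each with an adjusted p of 0.999.

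Cytosolic ribosomal protein genes also fell in P-deficient roots, by a smaller amount. The median of 24 genes was -0.33, with 22 lower, as in rps28 (-0.45, SE 0.2) and rpl5 (-0.3, SE 0.13), and 0 passed adjusted over the list alone. Their limma camera adjusted p was 4.8e-05, and adjusted p = 0.723 with an estimated correlation, and the call was lost with normexp (median -0.14, limma adjusted p 0.0629). Histone and cell cycle genes (median -0.3) and reference genes (median -0.31) were shifted by a similar amount without being called. The phosphate transporter pht2 had the smallest p of the 8 Pi transport genes, at 2.09 ± 0.36 (SD, n = 3) in Control and 2.85 ± 0.24 in P-deficient roots, a change of 0.76 (SE 0.26, limma adjusted p 0.999). The Pi transport list had a median of 0.07 but a mean of -0.06 (camera adjusted p 0.604 in limma, direction up). PHR1, a MYB-type regulator of the phosphate starvation response, was within -0.07 and 0.11 of no change in all 14 comparisons. Over all 32167 probes limma called 0 in this comparison, with 943 at an unadjusted p under 0.05 where chance gives 1608. With the slide as a block the phytosiderophore median was -1.5 (limma camera adjusted p 3.1e-04) and the ribosomal median -0.34 (3.6e-05), and with the scan day as a block they were -1.62 (1.8e-05) and -0.29 (7.2e-05). Within slides 3 and 5 the median differences over the genes were -1.17 and -0.76 for phytosiderophore genes and -0.24 and -0.34 for ribosomal genes, and within days 2 and 3 they were -1.17 and -1.22, and -0.24 and -0.32.

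**Figure D2:**
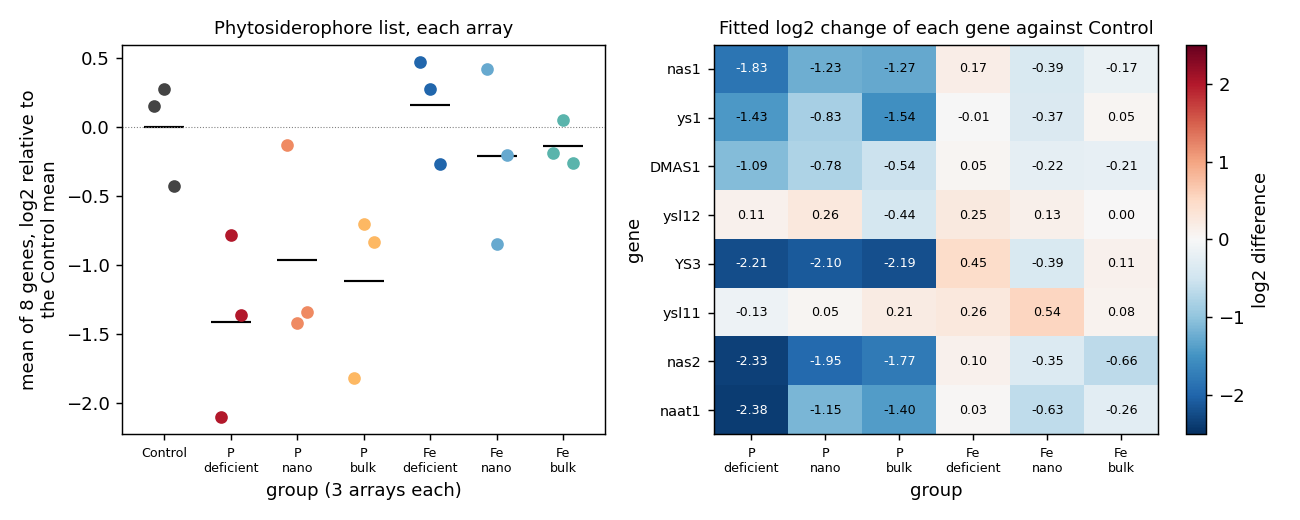
On the left, each point is the mean log2 signal of the 8 phytosiderophore genes on 1 array relative to the Control mean, by group, with bars at group means. On the right, each cell is the fitted log2 change of 1 gene against Control, where naat1 reads -2.38 in P-deficient and 0.03 in Fe-deficient roots.

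Iron withdrawal was compared with the complete solution in the same way. A single probe fell, that of GRMZM2G138450, a gene model with no name in the table, chosen after its values were seen. Its signal was 5.68 ± 0.21 (SD, n = 3) in Control and 0.53 ± 0.36 in Fe-deficient roots, a change of -5.15 (interval -6.1 to -4.21) or 35.6-fold. All 3 Fe-deficient arrays lay below all 3 Control arrays, each well above background, and its limma adjusted p was 8.7e-05. In P-deficient roots it was at 4.1 ± 0.18, a difference of -1.58 from Control (limma adjusted p 0.999). The phytosiderophore genes had a list median of 0.14 (limma camera adjusted p 0.578), with nas1 at 0.17 (SE 0.68) and naat1 at 0.03 (SE 0.57). The member with the smallest p was ysl11, at 0.26 (SE 0.31, limma adjusted p 0.982), and among Pi transporters it was pht7, at -0.74 (SE 0.54, limma adjusted p 0.982). The iron storage gene fer1, a ferritin, was at 2.04 ± 0.15 in Control and 1.22 ± 0.59 in Fe-deficient roots (limma adjusted p 0.982).

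Ribosomal protein genes fell in Fe-deficient roots too, with a median of -0.34 and 19 of 24 genes lower, as in rpl12 (-0.47, SE 0.22) and rpl5 (-0.32, SE 0.13). The camera adjusted p from limma was 4.9e-04, and adjusted p = 0.936 with an estimated correlation. Adjusted over the list alone 0 members passed. The call was lost in limma without Control replicate 1 (adjusted p 0.253) and with normexp (median -0.15, adjusted p 0.264). Normexp also moved the median of all probes, and less that median the list was at -0.69, against -0.39 without normexp. Limma called 1 probe over all probes, with 1165 at an unadjusted p under 0.05. With the slide as a block GRMZM2G138450 changed by -4.72 (limma adjusted p 0.0208) and the ribosomal median was -0.36 (0.0123), and with the scan day as a block these were -4.95 (1.2e-04) and -0.41 (7.4e-05). Within slide 2 the differences were -5.26 for GRMZM2G138450 and -0.32 for the ribosomal median, and within days 1 and 2 they were -5.49 and -4.6, and -0.24 and -0.62.

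**Figure D3:**
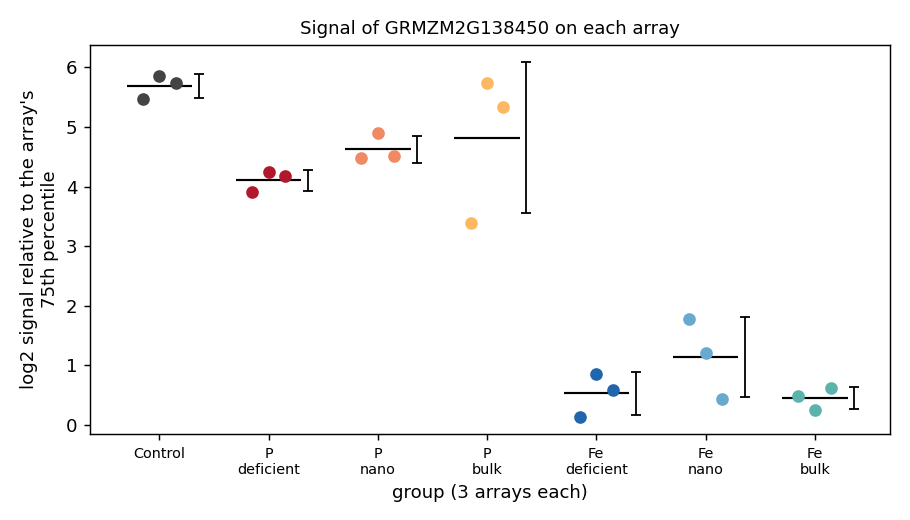
Each point is the log2 signal of GRMZM2G138450 on 1 array, relative to the array's 75th percentile, by group, with bars at means and whiskers of 1 SD (n = 3). The 9 arrays without FeNaEDTA lie below the others, with means of 0.53, 1.14 and 0.45 against 4.1 to 5.68.

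The direct comparison of the deficiencies asks whether roots respond differently to the loss of phosphate and of iron. Phytosiderophore genes were lower in P-deficient than in Fe-deficient roots, with a median of -1.71 and 8 of 8 genes lower. YS3 differed by -2.66 (SE 0.82), nas2 by -2.43 (SE 0.79), naat1 by -2.41 (SE 0.57) and nas1 by -2 (SE 0.68). The limma camera adjusted p was 2.2e-09, and adjusted p = 0.0594 with an estimated correlation, and with normexp the median was -0.92 (limma adjusted p 0.189). Less the median of all probes the list was at -0.47 with normexp, against -1.64 without it. Adjusted over the list alone 6 of 8 passed, and 0 over all probes. GRMZM2G138450 was 11.9-fold higher in P-deficient roots, by 3.57 (interval 2.63 to 4.52, limma adjusted p 0.015), and was the 1 probe called, with 1633 at an unadjusted p under 0.05.

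The ferritin gene fer1 differed by 1.43 (SE 0.53, limma adjusted p 0.814) and the metal transporter Nramp1 by -0.73 (SE 0.31), while pht2 differed by 0.61 (SE 0.26), with the same adjusted p. P-deficient and Fe-deficient arrays shared no slide. Blocking on the slide, the phytosiderophore median was -2 (limma camera adjusted p 9.9e-07) and GRMZM2G138450 differed by 3.05 (limma adjusted p 0.196). With the scan day as a block these were -1.69 (3.9e-08) and 3.16 (0.0884), and within day 2 they were -1.27 and 3.39. The call of GRMZM2G138450 in limma was lost without P-deficient replicate 1, 2 or 3 (adjusted p 0.0911, 0.124 and 0.143), without Fe-deficient replicate 1, 2 or 3 (0.197, 0.065 and 0.12), and with only the 6 arrays compared (0.0674).

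FePO4 nanoparticles and bulk FePO4 were each compared with P-deficient roots to ask whether they replaced the missing phosphate. In P-nano roots the photosynthesis genes, included as markers of shoot tissue, fell with a median of -0.9 and 8 of 10 lower (adjusted p = 0.719 with an estimated correlation), among them the light-harvesting genes lhcb5 (-1.08, SE 0.64) and lhcb7 (-1.23, SE 0.89). The list is dim in roots, with its median signal at the 8.7th percentile, and lhcb5 was well above background on 2 of 3 and lhcb7 on 1 of 3 P-nano arrays. For cab48 and lhcb4, on 0 P-nano arrays well above background, no difference from P-deficient roots is bounded away from 0, and with both at 0 the median was -0.6 with 6 of 10 lower. The phytosiderophore genes were not called, with a median of 0.35 (limma camera adjusted p 0.134). The smallest p was that of naat1, at 1.23 (interval 0.02 to 2.44, limma adjusted p 1), and among Pi transporters that of pht6, at 1.27 (SE 0.53, limma adjusted p 1). Over all probes limma called 0, with 824 at an unadjusted p under 0.05. The photosynthesis list had a camera adjusted p of 0.0184 in limma, with 0 members passing adjusted over the list alone. With slide and scan day as blocks its median was -1.08 (limma adjusted p 0.00107) and -0.82 (0.0456), and the median difference over the genes was -1.3 within slide 6 and -0.29 and -0.37 within days 2 and 3. With normexp the median was -0.13 (limma adjusted p 0.736). The mean of this list over 21 arrays rose with the percent of probes well above background (r = 0.69, p = 5e-04, Spearman rho = 0.64, p = 0.0024, and r = 0.68, p = 0.0014 without Fe-bulk replicate 3 and Fe-nano replicate 1), a relation looked at after the values were seen. The call was lost in limma without P-deficient replicate 1 (adjusted p 0.652) or 2 (0.236), or P-nano replicate 1 (0.328) or 3 (0.0626). In a model with the slide as a block the phytosiderophore median was 0.9 (limma camera adjusted p 0.0134).

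In P-bulk roots ribosomal protein genes rose against P-deficient roots, with a median of 0.23 and 20 of 24 higher, as in rpl12 (0.67, SE 0.22) and rpl5 (0.42, SE 0.13). Limma's camera adjusted p was 0.00248, and adjusted p = 0.825 with an estimated correlation, and 0 members passed adjusted over the list alone. Phytosiderophore genes had a median of 0.44 (limma camera adjusted p 0.53), with naat1 at 0.98 (SE 0.57), and pht1 had the smallest p among Pi transporters at -0.37 (SE 0.25, limma adjusted p 1 for both). Of all probes 0 were called by limma, with 711 at an unadjusted p under 0.05. With slide and scan day as blocks the ribosomal median was 0.23 (limma adjusted p 0.00331) and 0.2 (0.00495), and the median difference over the genes was 0.05 and 0.07 within slides 3 and 5, and 0.05 and 0.11 within days 2 and 3. The call was lost in limma without P-deficient replicate 1 (adjusted p 0.271) or 3 (0.205), or P-bulk replicate 1 (0.0599) or 2 (0.0919), and with normexp (median 0.05, 0.468). Relative to the median of all probes the list was at 0.41 with normexp, against 0.2 without it.

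Nanoparticles against bulk FePO4 as the phosphate source showed lower ribosomal protein genes in P-nano roots, with a median of -0.15 and 20 of 24 lower, as in rpl12 (-0.6, SE 0.22). Its limma camera adjusted p was 0.0357, and adjusted p = 0.775 with an estimated correlation, with 0 members passing adjusted over the list alone. Phytosiderophore genes had a median of 0.06 (limma camera adjusted p 0.515). The transporter ysl12 differed by 0.7 (interval -0.04 to 1.44) and ys1 by 0.71 (interval -0.34 to 1.77), and pht12 by -0.89 (SE 0.48), on 1 of 3 P-nano and 2 of 3 P-bulk arrays well above background. Probe by probe, limma called 0, with 741 at an unadjusted p under 0.05. With the slide as a block the ribosomal median was -0.19 (limma adjusted p 0.121) and with the scan day as a block -0.15 (0.0237), and the median difference over the genes was -0.3 within slide 1 and -0.3, -0.2 and 0 within days 1, 2 and 3. The call was lost in limma without P-nano replicate 1 (adjusted p 0.121) or 3 (0.254), P-bulk replicate 1 (0.324) or 2 (0.242), or Fe-nano replicate 1 (0.0513), with quantile normalization (0.109) and with normexp (median -0.09, 0.26). Less the median of all probes the ribosomal list was at -0.35 with normexp, against -0.11 without it.

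Roots given FePO4 for phosphate were also compared with the complete solution. In P-nano roots the phytosiderophore median was -0.99 with 6 of 8 lower, a call lost with the slide as a block (median -0.65, limma camera adjusted p 0.59) and, at adjusted p = 0.727, with an estimated correlation. The largest differences were those of YS3 (-2.1, SE 0.82) and nas2 (-1.95, SE 0.79), the latter well above background on 2 of 3 P-nano arrays. The ribosomal median was -0.32 with 22 of 24 lower, and the photosynthesis median -0.85 with 9 of 10 lower. The light-harvesting gene cab48 was well above background on all 3 Control and on 0 P-nano arrays and was at least 1.61-fold lower, the 1 photosynthesis gene that passed adjusted over the list alone. With cab48 and lhcb4, also well above background on 0 P-nano arrays, at their bounds the photosynthesis median was -0.71. The limma camera adjusted p was 7.0e-04 for phytosiderophore genes, 1.4e-04 for ribosomal genes (adjusted p = 0.727 with an estimated correlation) and 8.0e-04 for photosynthesis genes (adjusted p = 0.727 with an estimated correlation). Adjusted over the list alone 0 phytosiderophore and 0 ribosomal genes passed. There were 0 limma calls over all probes, with 864 at an unadjusted p under 0.05, and pht2 was at 0.68 (SE 0.26, limma adjusted p 1).

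P-nano and Control shared no slide, so no difference within a slide can be given. With the slide as a block the phytosiderophore median was -0.65 (limma camera adjusted p 0.59), the ribosomal -0.27 (0.0107) and the photosynthesis -1.91 (4.8e-07). With the scan day as a block they were -0.99 (0.00332), -0.32 (1.2e-04) and -0.85 (0.00235). Within days 1, 2 and 3 the median difference over the phytosiderophore genes was -0.31, -1.74 and -0.94, over the ribosomal genes -0.17, -0.43 and -0.19, and over the photosynthesis genes -1.92, -0.51 and -0.36. Without Control replicate 1 the ribosomal adjusted p in limma was 0.0929 and the photosynthesis one 0.0513, and without P-nano replicate 1 the photosynthesis one was 0.351. With normexp the photosynthesis median was -0.1 (limma adjusted p 0.591), the phytosiderophore one -0.35 and the ribosomal one -0.14.

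In P-bulk roots phytosiderophore genes fell against Control with a median of -1.33 and 7 of 8 lower, led by YS3 (-2.19, SE 0.82) and nas2 (-1.77, SE 0.79). The member with the smallest p was ys1, at -1.54 (SE 0.5, limma adjusted p 1). The limma camera adjusted p was 2.6e-05, and adjusted p = 0.356 with an estimated correlation, and 0 members passed adjusted over the list alone. The transporter pht2 was at 0.66 (SE 0.26, limma adjusted p 1). Limma called 0 probes, with 782 at an unadjusted p under 0.05. Photosynthesis genes, markers of shoot tissue, had a mean of -0.66 relative to Control (limma camera adjusted p 0.0632). Camera called them lower with quantile normalization (adjusted p 0.0362), the replicate block (0.0386) and the slide block (0.0236). With slide and scan day as blocks the phytosiderophore median was -1.29 (limma adjusted p 3.7e-04) and -1.33 (1.0e-04), and the median difference over the genes was -1.11 and -0.4 within slides 3 and 5, and -2.61, -1.11 and -0.4 within days 1, 2 and 3.

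FePO4 as the iron source was compared with Fe-deficient roots to ask whether either form replaced FeNaEDTA. No list was called for either form, and GRMZM2G138450 stayed near its Fe-deficient level, differing by 0.6 (interval -0.34 to 1.55) in Fe-nano and -0.08 (interval -1.02 to 0.87) in Fe-bulk roots. Phytosiderophore genes had medians of -0.41 in Fe-nano and -0.28 in Fe-bulk roots (limma camera adjusted p 0.227 and 0.29). The members with the smallest p were naat1 in Fe-nano (-0.66, SE 0.57) and nas2 in Fe-bulk roots (-0.76, SE 0.79). Among Pi transporters they were pht7 in Fe-nano (0.92, SE 0.54) and pho1 in Fe-bulk roots (0.29, SE 0.2), and fer1 differed by 0.95 (SE 0.53) in Fe-nano roots. All of these had a limma adjusted p of 1. Limma called 0 probes for Fe-nano, with 720 at an unadjusted p under 0.05, and 0 for Fe-bulk, with 191. With the scan day as a block limma's camera called ribosomal proteins higher in Fe-nano (median 0.25, adjusted p 0.00115) and Fe-bulk roots (0.12, 0.0372), against 0.18 (0.0805) and 0.13 (0.29) without it and 0.2 (0.0924) and 0.1 (0.39) with the slide as a block.

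Between the forms of the iron source, cell wall loosening genes were higher and glutathione S-transferase genes lower in Fe-nano than in Fe-bulk roots. Of 14 cell wall genes 13 were higher, with a median of 0.35, as in the expansins expB3 (1.05, SE 0.65) and EXPA5 (0.52, SE 0.33). Of 29 glutathione S-transferases, which conjugate glutathione to reactive compounds, 17 were lower and 12 higher, with a median of -0.16, as in gst42 (-0.59, SE 0.28), gst9 (-0.74, SE 0.39) and GST3 (0.28, SE 0.16). The limma camera adjusted p was 0.0405 for cell wall genes (adjusted p = 0.602 with an estimated correlation) and 0.0413 for glutathione S-transferases (adjusted p = 0.54 with an estimated correlation). Adjusted over the list alone 0 members of either passed. Phytosiderophore genes had a median of -0.11 (limma camera adjusted p 0.876), with ysl11 at 0.46 (SE 0.31), and pht7 differed by 0.64 (SE 0.54). Limma called 0 probes, with 860 at an unadjusted p under 0.05.

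For these lists with the slide as a block the cell wall median was 0.46 (limma adjusted p 0.129) and the glutathione S-transferase median -0.13 (0.138), and with the scan day as a block 0.41 (0.0254) and -0.11 (0.259). Within slide 2 the median differences over the genes were 0.28 and -0.04, and within days 1 and 3 they were 0.07 and 0.32 for cell wall genes and -0.24 and -0.04 for glutathione S-transferases. The mean over the glutathione S-transferases differed by -0.35 within slide 2, by -0.4 within day 1 and by 0.39, in the other direction, within day 3. The cell wall call was lost in limma without Fe-nano replicate 1 (adjusted p 0.131) or 3 (0.334) or Fe-bulk replicate 1 (0.332), and with normexp (median 0.1, 0.425). The glutathione S-transferase call was lost without Fe-nano replicate 2 (0.457) or 3 (0.112) or Fe-bulk replicate 1 (0.0858) or 2 (0.373), with the replicate block (0.0693), quantile normalization (0.108) and normexp (median -0.71, 0.589). Relative to the median of all probes, cell wall genes were at 0.59 with normexp and 0.3 without it. Glutathione S-transferases were at -0.21 in both settings on that scale.

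Against the complete solution GRMZM2G138450 fell in both iron-source groups, with a change of -4.55 in Fe-nano (interval -5.5 to -3.6, 23.41-fold) and of -5.23 in Fe-bulk roots (interval -6.18 to -4.28, 37.55-fold). The limma adjusted p was 5.3e-04 and 7.0e-05, and all 3 arrays of each group lay below all 3 Control arrays. Phytosiderophore genes had medians of -0.36 in Fe-nano and -0.08 in Fe-bulk roots (limma camera adjusted p 0.786 and 0.973), the latter tested as higher although its median was negative. The smallest p belonged to ysl11 in Fe-nano (0.54, SE 0.31) and nas2 in Fe-bulk roots (-0.66, SE 0.79), and among Pi transporters to pht12 (0.72, SE 0.48) and pht1 (-0.37, SE 0.25). Limma called 1 probe in each, with 1423 and 720 at an unadjusted p under 0.05, and 0 lists. Blocking on the slide, GRMZM2G138450 changed by -4.1 (limma adjusted p 0.057) in Fe-nano and -5.23 (9.0e-04) in Fe-bulk roots, with the scan day as a block by -4.33 (7.3e-04) and -5.23 (4.1e-05). With only the 6 arrays compared the limma adjusted p for Fe-nano was 0.399. Its difference within slide 2 was -5.43 for Fe-nano, and within slides 2, 3 and 5 it was -5.6, -4.97 and -5.12 for Fe-bulk. Within days 1 and 3 it was -5.04 and -3.97 for Fe-nano, and within days 1, 2 and 3 it was -5.6, -4.97 and -5.12 for Fe-bulk.

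The difference between nano and bulk FePO4 was compared across the phosphate and iron supply. Phytosiderophore transporter ys1 had the smallest p of its list, with a difference of 1.14 (SE 0.71), and pht12 that of the Pi transport list, at -0.97 (SE 0.67), both with a limma adjusted p of 1. Limma called 0 probes, with 1107 at an unadjusted p under 0.05, and camera called 0 lists. Ribosomal proteins, with a median of -0.27 (limma camera adjusted p 0.0946), were called lower with the scan day as a block (-0.32, 0.0224) and with the mean over the probes of a gene (0.0259), and were not with the slide as a block (-0.27, 0.13).

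Changes that shared a reference group were correlated across genes, which are not independent replicates. Unchanged groups simulated against 1 shared reference gave a mean r of 0.49 (0.01 to 0.81) and a mean covariance of 0.1 (0 to 0.27) over 100 draws. The observed r was 0.32 for P-deficient and Fe-deficient against Control (covariance 0.05), 0.52 for P-nano and P-bulk against P-deficient (0.07) and 0.42 for Fe-nano and Fe-bulk against Fe-deficient (0.05). Against Control it was 0.48 for P-deficient with P-nano (0.07), 0.66 for P-deficient with P-bulk (0.11), 0.62 for Fe-deficient with Fe-nano (0.11) and 0.71 for Fe-deficient with Fe-bulk (0.11). GRMZM2G138450 was the 1 call shared in each of the last 2, where independent lists share 3e-05. With 3 arrays the reference could not be split, so part of any excess may come from it.

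The other 16 tested lists were not called in any comparison, though the slide block and normexp called 5 of them, given below with the other settings. The smallest limma camera adjusted p over all comparisons was 0.397 for Pi transport and for glycolytic bypass genes (P-deficient against Fe-deficient), 0.278 for nitrate and 0.237 for sulfate uptake (P-bulk against Control), and 0.189 for class III peroxidases (P-nano against P-deficient). In P-nano against P-bulk it was 0.191 for antioxidant enzymes and for phenylpropanoid genes and 0.267 for heat shock proteins, and in Fe-nano against Fe-bulk 0.255 for aquaporins and 0.102 for kernel genes. For P-deficient against Control, limma's camera gave 0.0681 for histones and cell cycle, 0.101 for reference genes and 0.0908 for defence proteins, which were tested as higher with a median of -0.03. It was 0.353 for ethylene synthesis (P-nano against Control), 0.29 for auxin response (Fe-bulk against Fe-deficient) and 0.114 for cytokinin response (Fe-deficient against Control). Genes of the lists too small to test had no limma call, with IDI2 of methionine salvage at -0.62 in P-nano against Control, ZIP4 at 0.48 in P-deficient against Fe-deficient, the root hair gene rth3 at -0.31 in Fe-bulk against Control, and the cellulose synthases cesa11 at 0.31 across supplies and CesA12 at 0.34 in P-bulk against Control.

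**Figure D4:**
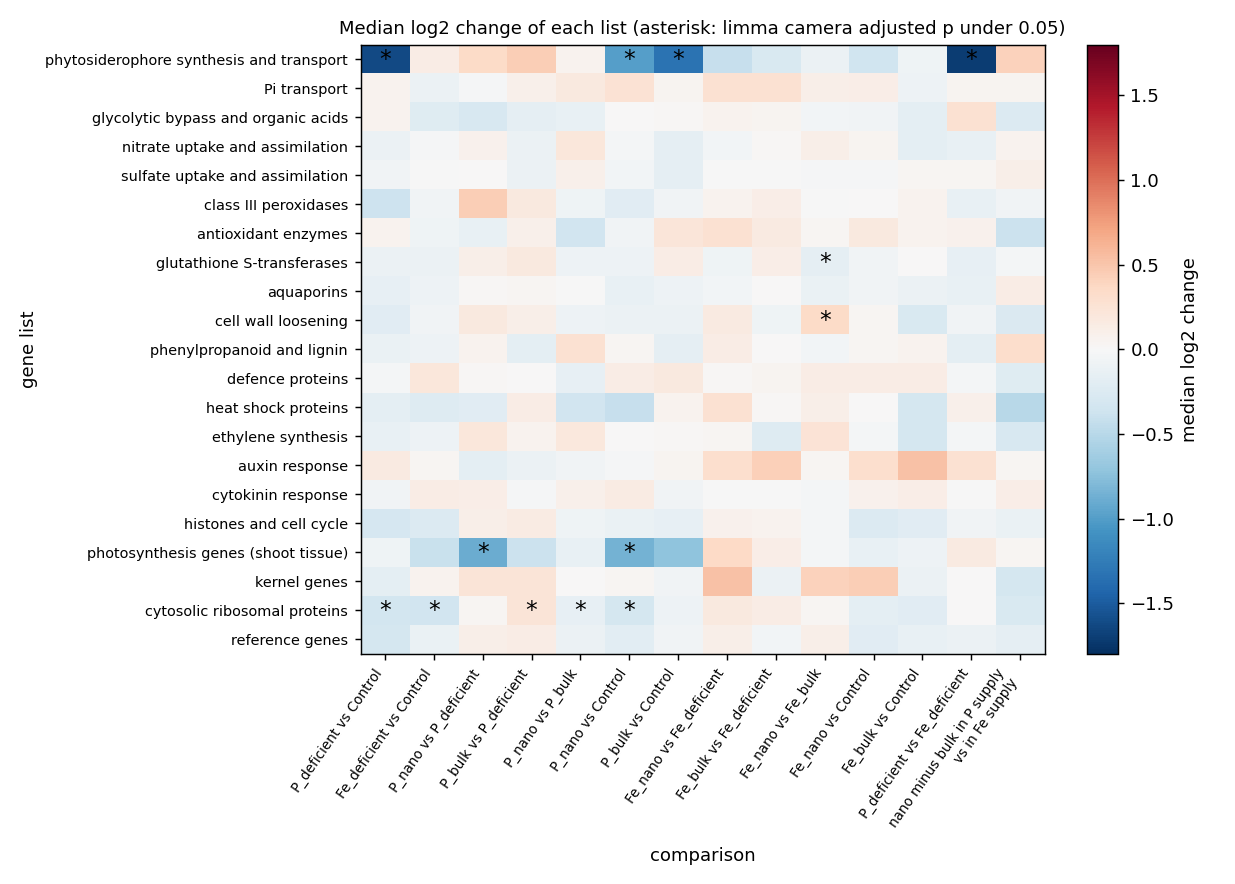
Each cell is the median log2 change of 1 gene list (rows) in 1 comparison (columns), and an asterisk marks a limma camera adjusted p under 0.05. Of 13 marked cells, 4 are phytosiderophore genes, between -1.71 and -0.99, and 5 are ribosomal proteins, between -0.34 and 0.23.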

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

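The slide and permutation tests of the phytosiderophore list, the 3 tests of GRMZM2G138450, the test of the share of probes above background and the splits for counts of probes in single comparisons were chosen after the results were seen. Of the results, 2 stood out because the effects of the deficiencies differed in a direct test. The median of the phytosiderophore genes differed by -1.71 between P-deficient and Fe-deficient roots, with adjusted p = 0.0594 with an estimated correlation and 0.189 with normexp. GRMZM2G138450 differed by 3.57, a limma call lost with the slide (difference 3.05, adjusted p 0.196) or the scan day (3.16, 0.0884) as a block and without any 1 of the 6 arrays (0.065 to 0.197).

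Phytosiderophore genes were lower in the 3 groups without KH2PO4, and pooled over these arrays so were photosynthesis genes, markers of shoot tissue (median -0.44, limma camera adjusted p 0.0059, and adjusted p = 0.7 with an estimated correlation). Among 10000 random lists of the same brightness the lowest median was -0.501, which puts the list's -1.63 in P-deficient roots at percentile 0 and argues against a shift of genes of this brightness. The slide as a block, at the preset correlation, left the list called in P-deficient and P-bulk roots (larger limma camera adjusted p 3.7e-04). Without a block, that correlation also called up to 3 and 2 lists in other splits of these arrays with those of Control. A call kept there therefore cannot exclude the slide, and a slide block with an estimated correlation was not run. Within slides 3 and 5, with 1 array of each group, the median differed from Control by -1.17 and -0.76 in P-deficient roots. In P-bulk roots it differed by -1.11 and -0.4. In P-nano roots, which shared 0 slides with Control and are linked to it through slides of other groups, the blocked adjusted p in limma's camera was 0.59 (median -0.65), so the slide stays open there too. A permutation of 9 arrays against 12 gave p = 9e-05 (difference -1.12, 100000 resamples), but list and grouping were picked after the list was seen low, and pooled over these arrays adjusted p = 0.0557 with an estimated correlation, so chance stays open. A response to the missing KH2PO4 may lie behind the pattern, as a hypothesis found on these data, and the list's call did not survive an estimated correlation (adjusted p = 0.264 in P-deficient roots). P-nano and P-bulk kept 100 uM FeNaEDTA and received FePO4 as well. They therefore also differ from Control by added iron, which cannot be told apart there from the missing KH2PO4.

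GRMZM2G138450 was lower on the 9 arrays without FeNaEDTA. With the slide as a block the difference over these arrays had a limma adjusted p of 7.0e-05, which argues against the slide, and it was well above background on 9 of 9 arrays, which argues against a signal at background. In the 3 comparisons with Control, fixed in advance, the largest limma adjusted p over 32167 probes was 5.3e-04, which argues against chance. These comparisons share the same Control arrays and are not independent. Pooled over the 9 arrays, without a block and in a grouping chosen after the values were seen, the difference was -4.1 (SE 0.24, limma adjusted p 2.4e-07). In single comparisons with the slide as a block limma's adjusted p was 0.0208 (Fe-deficient), 0.057 (Fe-nano) and 9.0e-04 (Fe-bulk). A response to the missing FeNaEDTA may lie behind it, as a hypothesis, and FePO4 in either form went with a level near that of Fe-deficient roots. Fe-nano and Fe-bulk kept 0.1 mM KH2PO4, so they also differ from Control by the phosphate added with FePO4.

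Arrays of 1 group differed widely. The slide held 35.3% of the variance between arrays (permuted median 24.7%, permutation p = 0.0132) and the treatment 28.2% (permuted median 29.7%, permutation p = 0.634). The first principal component followed the percent of probes well above background over 21 arrays (r = -0.72, p = 2e-04, Spearman rho = -0.77, p = 1e-04, and r = -0.77, p = 1e-04 without Fe-bulk replicate 3 and Fe-nano replicate 1). Slide and signal over background may each carry part of this variation. With array weights limma called 2117 probes between Fe-bulk and Fe-deficient roots and at most 393 in the 9 other splits of the 6 arrays, and 10 splits are too few to weigh chance.

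With 3 arrays against 3 there are 10 splits, too few for a share under 0.05. Counts of splits given below include the real one. By limma, the count of probes in P-deficient against Control was 0 with 943 at an unadjusted p under 0.05, a count that 10 of 10 splits reach whatever the data, and the highest other count was 71. That split set all 3 arrays of scan day 3, on slides 5 and 6, against those of days 1 and 2, on slides 2 and 3. Scan day and slide cannot be told apart there. With the scan day as a block the real count was 0. In the other 8 comparisons with 0 limma calls, at the unadjusted counts given with each, 10 of 10 splits likewise reach the count, with a highest other count of 0. In the 4 comparisons with 1 call, only the real split of the 10 gave as many, and the highest other count was 0.

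For lists called by limma's camera, the real count, the highest other count and the splits with as many were 2, 3 and 5 for P-deficient, 1, 2 and 3 for Fe-deficient, 3, 4 and 3 for P-nano, 1, 2 and 6 for P-bulk, 0, 6 and 10 for Fe-nano, and 0, 2 and 10 for Fe-bulk, each against Control. Against P-deficient they were 1, 3 and 7 for P-nano and 1, 4 and 8 for P-bulk, and against Fe-deficient 0, 7 and 10 for Fe-nano and 0, 3 and 10 for Fe-bulk. They were 1, 3 and 6 for P-nano against P-bulk, 2, 4 and 5 for Fe-nano against Fe-bulk, and 1, 5 and 7 for P-deficient against Fe-deficient. For the difference between forms across supplies, where limma called 0 probes (1107 at an unadjusted p under 0.05) and 0 lists, 100 of 100 assignments of the 12 arrays reach these counts whatever the data, with highest other counts of 19 probes and 5 lists, so they say nothing on chance.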

How the results depend on the processing

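The normexp correction on the median signal, the scan day block, the slide block for lists, array weights, keeping non-uniform spots, leaving out Fe-nano replicate 1 from all comparisons and the pooled comparisons were chosen after the results were seen. Of the values under other settings 1378 were labelled the same, 94 were counts that moved, 65 were weaker, 3 were stronger and 0 reversed. This label stood for a similar count or correlation, the same side of the threshold for a gene, and also the same direction for a list. A gene's change of sign was labelled reversed only where a call was involved, so 0 reversed says little on genes not called. Among named genes 827 of 841 values were on the same side of the threshold. Genes not called in either setting also count as the same. Probe counts moved in 0 of 14 comparisons with no filter, the filter on all 21 arrays, the added limit on the log2 change, quantile normalization, trend and robust moderation, the authors' table, non-uniform spots kept and normexp. The added limit of 1 could not move a count, as the 1 called probe differed by at least 3.57, and the authors' table gives the same calls by construction. Signal over background limits the dim lists, such as photosynthesis genes. The replicate numbers were not taken as pairs, since the labels do not say that a number marks a shared repeat. Of 63 same-number pairs 26 had a correlation over 0.1 (mean 0.05 against -0.02 for other pairs) and 11 of 21 arrays correlated best with their own number, so a shared repeat stays open. The cause of the changes that follow was not tested.

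Counts of probes called by limma became 0 with the slide as a block in Fe-nano against Control and in P-deficient against Fe-deficient, 0 with the scan day as a block in the latter, and 0 in both with only the arrays compared. Leaving out 1 array gave 0 to 1 in P-deficient against Fe-deficient. Array weights, which reached 12.47 for P-nano replicate 2, 7.5 for Fe-deficient replicate 2, 7.41 for Fe-bulk replicate 2 and 3.56 for Fe-nano replicate 3, gave 10 (Fe-deficient), 194 (P-nano), 2 (Fe-nano) and 3 (Fe-bulk) against Control, 1 (P-nano against P-deficient), 1377 (Fe-nano) and 2117 (Fe-bulk) against Fe-deficient, 21 (P-nano against P-bulk), 488 (Fe-nano against Fe-bulk), 12 (P-deficient against Fe-deficient) and 384 across supplies. With these weights, YS3 was at -2.98 in P-nano against Control (limma adjusted p 0.0303), and pht7 at 1.74 (0.0128) and 1.96 (0.0134) in Fe-nano against Fe-deficient and Fe-bulk.

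With an estimated correlation 0 lists were called by limma's camera in P-deficient, Fe-deficient, P-nano and P-bulk against Control (0, 0, 0 and 0), P-nano and P-bulk against P-deficient (0 and 0), P-nano against P-bulk (0), Fe-nano against Fe-bulk (0) and P-deficient against Fe-deficient (0). The adjusted p for phytosiderophore genes was then 0.264 (P-deficient), 0.727 (P-nano) and 0.356 (P-bulk) against Control and 0.0594 in P-deficient against Fe-deficient. For ribosomal proteins it was 0.723 (P-deficient), 0.936 (Fe-deficient) and 0.727 (P-nano) against Control, 0.825 in P-bulk against P-deficient and 0.775 in P-nano against P-bulk. Photosynthesis genes had 0.719 in P-nano against P-deficient and 0.727 against Control, glutathione S-transferases 0.54 and cell wall loosening 0.602.

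Quantile normalization gave 0 lists in P-nano against P-bulk (ribosomal proteins 0.109), 2 in P-bulk against Control and 1 in Fe-nano against Fe-bulk (glutathione S-transferases 0.108). A replicate block gave 2 in P-bulk against Control and 1 in Fe-nano against Fe-bulk (glutathione S-transferases 0.0693), and changed no other call in the 14 comparisons. The list added in P-bulk against Control was photosynthesis genes (0.0362 and 0.0386). The mean over the probes of a gene gave 1 across supplies (ribosomal proteins, lower, 0.0259).

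The slide block gave 2 lists in Fe-deficient against Control, 2 in P-nano against P-deficient, 2 in P-bulk against Control, 0 in Fe-nano against Fe-bulk and 3 in P-deficient against Fe-deficient. It ended the calls of ribosomal proteins in P-nano against P-bulk (0.121), phytosiderophore genes in P-nano against Control (0.59), glutathione S-transferases (0.138) and cell wall loosening (0.129). It added calls of cytokinin response genes in Fe-deficient against Control (higher, 0.0123) and in P-deficient against Fe-deficient (lower, 0.0279), nitrate genes in the latter (lower, 0.0279), heat shock proteins in P-nano against Control (lower, 0.0144), phytosiderophore genes in P-nano against P-deficient (higher, 0.0134) and photosynthesis genes in P-nano against P-bulk (lower, 0.0106) and P-bulk against Control (lower, 0.0236). The scan day block gave 1 in Fe-nano and 1 in Fe-bulk against Fe-deficient (ribosomal proteins, higher, 0.00115 and 0.0372), 1 in Fe-nano against Fe-bulk (glutathione S-transferases 0.259) and 1 across supplies (ribosomal proteins, lower, 0.0224).

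Normexp gave 0 lists in Fe-deficient against Control, 0 in P-nano against P-deficient, 0 in P-bulk against P-deficient, 0 in P-nano against P-bulk, 0 in Fe-nano against Fe-bulk, 0 in P-deficient against Fe-deficient and 1 in Fe-nano against Control (histones and cell cycle, lower, 0.0332). It added defence proteins (higher) and histones and cell cycle genes (lower) in P-deficient against Control (0.0233 for both) and in P-nano against Control (0.0132 and 0.0142). Ribosomal proteins had an adjusted p of 0.0629 (P-deficient) and 0.264 (Fe-deficient) against Control, 0.468 in P-bulk against P-deficient and 0.26 in P-nano against P-bulk. Photosynthesis genes had 0.736 in P-nano against P-deficient and 0.591 against Control, glutathione S-transferases 0.589, cell wall loosening 0.425, and phytosiderophore genes 0.189 in P-deficient against Fe-deficient. The phytosiderophore median in P-deficient roots less that of all probes was -1.56, and was -1.57 with quantile normalization and -0.58 with normexp.

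Leaving out each array gave, for lists called against Control, 2 to 4 (P-deficient), 0 to 2 (Fe-deficient), 1 to 3 (P-nano), 1 to 2 (P-bulk), 0 to 2 (Fe-nano) and 0 to 1 (Fe-bulk). It gave 0 to 3 and 0 to 1 for P-nano and P-bulk against P-deficient, 0 to 3 and 0 to 1 for Fe-nano and Fe-bulk against Fe-deficient, 0 to 1 for P-nano against P-bulk, 0 to 2 for Fe-nano against Fe-bulk, 1 to 2 for P-deficient against Fe-deficient and 0 to 1 across supplies. The adjusted p of ribosomal proteins ranged over 1.5e-05 to 0.253 (Fe-deficient against Control), 4.5e-05 to 0.0929 (P-nano against Control), 1.5e-06 to 0.271 (P-bulk against P-deficient) and 2.3e-04 to 0.324 (P-nano against P-bulk). That of photosynthesis genes ranged over 1.2e-05 to 0.351 (P-nano against Control) and 4.2e-07 to 0.652 (P-nano against P-deficient), of glutathione S-transferases over 0.00732 to 0.457 and of cell wall loosening over 0.00364 to 0.334. Phytosiderophore calls held without each array in turn.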

Other observations

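All comparisons in this part, which pool groups, were chosen after the results were seen, and so were the genes named here, while the counts of other assignments of the arrays were chosen before. Pooled over the 9 arrays without FeNaEDTA, limma called 30 probes against the 12 others, 3 higher and 27 lower (5035 at an unadjusted p under 0.05). The 12 others include the 9 without KH2PO4, so a call can also come from a difference on those arrays. GRMZM2G065989, among the 27 (-1.58), had a mean of -1.75 without FeNaEDTA and 0.34 without KH2PO4. Over the 12 arrays with KH2PO4, Control among them, its mean was -1.73. Besides GRMZM2G138450 (-4.1, SE 0.24, adjusted p 2.4e-07, and 7.0e-05 with the slide as a block), GRMZM2G074761 was lower by limma (-1.78, SE 0.18, adjusted p 3.2e-04, slide block 0.00245), as was GRMZM2G318652 (-1.43, SE 0.17, adjusted p 0.00145, slide block 0.00178), and GRMZM2G350312 was higher (1.27, SE 0.14, adjusted p 5.7e-04, slide block 0.00959), each beyond all other arrays on 9 of 9. The 9 arrays without KH2PO4 had 15 limma calls, 14 higher and 1 lower (4168 at an unadjusted p under 0.05). Since the 12 others here include the 9 without FeNaEDTA, 14 of these 15 were also among the 30, with the opposite sign, and GRMZM2G138450 was higher by 2.57 although it was lower than Control in P-deficient (-1.58), P-nano (-1.06) and P-bulk roots (-0.86). Among the 15 were GRMZM2G065989 (2.07, SE 0.25, adjusted p 0.00297, slide block 0.0366, 9 of 9 arrays) and LOB15, a gene with a LOB-domain symbol (0.84, SE 0.13, adjusted p 0.0281, slide block 0.0735). Between the 2 sets of 9 arrays there were 32 limma calls, 29 higher and 3 lower without KH2PO4 (5215 unadjusted). With the slide as a block limma called 32 (18 higher, 14 lower), 23 (10 and 13) and 58 (22 and 36), so the directions were no longer one-sided, and 13 of the 30, 9 of the 15 and 18 of the 32 stayed called. With the scan day as a block the counts were 13 (3 and 10), 12 (11 and 1) and 24 (21 and 3), with quantile normalization 49 (5 and 44), 19 (19 and 0) and 47 (44 and 3), and with the replicate block 37 (4 and 33), 14 (13 and 1) and 34 (31 and 3), where 3, 5 and 5 of the first calls were lost. Without Fe-nano replicate 1 they were 19 (2 and 17), 9 (8 and 1) and 24 (22 and 2). Of 100 assignments of the 21 arrays, the real one included, 4, 3 and 3 gave as many, under 5 in 100. Only 4, 3 and 4 of the random assignments gave any call at all, so a single call would have ranked nearly as high. As the groupings were chosen after GRMZM2G138450 was seen to differ, these ranks cannot decide whether the further calls arose by chance. Single random assignments gave up to 3812, 1302 and 2975 probes, and whether these follow slide, scan day or another structure was not tested.

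Photosynthesis genes were lower on the arrays without KH2PO4 than on those without FeNaEDTA (median -0.46, limma camera adjusted p 0.018, and adjusted p = 0.635 with an estimated correlation). Pooled over both nutrients, nano against bulk FePO4 gave 0 limma calls (449 at an unadjusted p under 0.05), and FePO4 against deficiency 0 (576 unadjusted). Cell wall loosening genes were higher with nano than with bulk FePO4 (median 0.13, limma camera adjusted p 0.00767, and adjusted p = 0.473 with an estimated correlation). In the iron supply alone the median was 0.35 with 13 of 14 higher (adjusted p = 0.602 with an estimated correlation). In the phosphate supply it was -0.09 with 8 of 14 lower, tested as higher (limma camera adjusted p 0.282), and the difference between supplies was not called (median -0.26, limma camera adjusted p 0.697). Ribosomal proteins were higher with FePO4 than in deficiency (median 0.12, limma camera adjusted p 9.5e-04, and adjusted p = 0.873 with an estimated correlation). The 2 largest differences among the 14 cell wall genes in P-nano against Control, where 8 were lower (median -0.11, tested as higher, limma camera adjusted p 0.69), were those of the beta-expansins expB3 and expB7. They stood at 3.45 ± 0.21 and 6.48 ± 0.19 (SD, n = 3) in P-nano and at 1.68 ± 0.36 and 4.93 ± 0.14 in Control, differences of 1.77 (SE 0.65) and 1.55 (SE 0.55) with a limma adjusted p of 1. Against P-bulk they differed by 1.58 and 1.47, also with a limma adjusted p of 1.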
